A study of Mus musculus with 189 samples.

How the data were processed

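The series was read from 1 deposited table with 189 columns, 1 per sorted cell, each matched to its label by name. The sort was on the green fluorescence of a Hopx reporter, and libraries were made with SMART-Seq2 and Tn5 tagmentation, per the labels' protocols. Adapter trimming with cutadapt, quantification with RSEM and the mm10 build are named per the submitters' processing notes, without versions. The deposited values carry the name TPM but are estimated counts: column totals differ from cell to cell, and of the nonzero values 81.3% at P3, 80.9% at P7 and 80.8% at P14 are whole numbers within 0.005. They were therefore treated as deposited expected (estimated) counts, and CPM, the count over the gene total of the cell times 1e+06, were used where TPM had been planned. The choice of unit was made after the values were seen. All log2 values are mean log2(CPM + 1) computed from the deposited counts. A difference on this scale understates the fold of genes at low level, and cells with no reads for a gene weigh heavily in it.

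The table held 15704 gene entries, 3 of them at 0 in every cell, and 3 annotation lines above the genes with the age, a cluster name and, for 109 cells, a pseudotime, all as deposited by the authors. GENCODE M21 gene symbols matched 15245 entries (97.1%), and coordinates are from that annotation on GRCm38. There were 20 entries whose names had become dates, which were kept as listed and not renamed. No doublet caller was run, since each well was meant to hold 1 cell, and no cell was left out of the main values. Cells with both Xist and a Y-linked transcript were kept. Reads carry no molecular identifiers, so intervals and limits from a count of 0 (3 counts over the cells of the age) cover counting error only. The strand of the reads is not given in the sources used here, so a gene and an antisense neighbour, such as Hopx and its antisense transcript, cannot be separated. The percent of nonzero counts that were whole served as a sign of reads that RSEM divided between genes of similar sequence.

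The ages were compared as 3 groups of 72, 54 and 63 cells in 3 comparisons. With no animal named in the labels each age was 1 sample, so no p-value was computed. Measured genes exceeded 1 CPM in at least 20% of the cells of 1 age. For each comparison the difference in mean log2(CPM + 1) was taken. For 45 gene lists, 30 of pathways and 15 of cell type markers, the median over measured members was set against 10000 random lists of the same size drawn from measured genes in 20 expression bins, for lists with at least 4 measured members. A list is said to stand apart outside percentiles 2.5 to 97.5, as a description of these cells and not a test. Members count as higher or lower at 1 log2 unit. Shares have exact Clopper-Pearson 95% intervals. The lists, these limits and the rule for named genes were fixed before the data were examined, in TPM, and the use of 0.5 log2 units as the least median given a direction was set afterwards.

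By that rule the text names the 12 highest and 12 lowest measured genes for P14 against P3 and the 8 highest and 8 lowest for the other comparisons, if the difference had the same sign and at least 50% of its size in odd and in even well columns. Predicted or unnamed models, Xist and Y-linked genes were passed over. A few genes that the rule takes are not reported here. From each list described, up to 4 members with the largest difference along the median and 1 or 2 against it could be named. Further genes named in the text, such as mt-Cytb, mt-Nd4, Mki67 and Insig1 among others, are list members or cell type markers, some of them picked after their values were seen. Within an age, 95% of genes differed by less than 1.49 (P3), 1.73 (P7) and 1.47 (P14) between cells of odd and even well columns.

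Cells were also clustered with scanpy 1.11.5 (Leiden, 4 clusters of 75, 46, 46 and 22 cells). These clusters matched the deposited ones poorly, with an adjusted Rand index of 0.279, and were not used for comparisons. The deposited cluster names were used as they stand. The procedure was tested on simulated data for P14 against P3 with 8266 genes, 200 of them changed and 20 more raised as a planted list. True log2 folds of 1 and 2 gave median differences of 0.72 and 1.36, and folds of -1 and -2 gave -0.56 and -0.97, with the right sign in 88.0%, 100.0%, 86.0% and 92.0% of genes. The planted list of 20 genes lay at percentile 99.91, and 4% of 200 unchanged lists stood apart. Simulated genes were drawn independently of each other, in cells without clusters. The 4% therefore does not tell how often lists of genes that vary together would stand apart.

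Alternatives covered the pseudocount (0.1 and 10), log2 ratios of mean CPM, the detection minimum, centring, leaving mitochondrial and ribosomal protein genes out of the total, subsets of cells by detected genes, cycling call and well column, and the clustering resolution. Thinning to 50000 reads (16 shallower cells left out), scaling by exon length and the 3 alternatives on deposited clusters were chosen after seeing the data. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.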

Results

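The series holds single cells sorted from the dentate gyrus, the hippocampal region in which neurons are made throughout life, of C57BL/6 mice that carry a Hopx-GFP reporter. Hopx encodes a small homeodomain protein, and the labels call every sorted cell a quiescent neural stem cell. Transcripts were read with SMART-Seq2, a full-length method that handles 1 cell per well. The cells came from postnatal day 3 (P3, 72 cells), day 7 (P7, 54 cells) and day 14 (P14, 63 cells), and the comparison of the 3 ages asks how stem cells differ along the route to their adult state. No label names an animal. Each age therefore counts as 1 sample, with no replicates, and differences are given with the SD over cells and without a test.

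Depth differed between the ages. The median estimated read count per cell was 177011 at P3, 447431 at P7 and 333223 at P14, and single cells ranged from 3875 to 5104200. The median number of genes above 1 CPM (the count scaled to the total of the cell) was 2987 at P3 (SD 913 over cells), 3534 at P7 (SD 1137) and 2779 at P14 (SD 1089). In total 6811 genes exceeded 1 CPM in at least 20% of the cells of 1 age and are called measured. Their median difference in mean log2(CPM + 1) was 0.26 for P7 against P3, -0.54 for P14 against P7 and -0.28 for P14 against P3. Medians of gene lists over all cells are mostly given with their value after subtracting this shift. Medians within clusters, in subsets of cells or as log2 ratios of mean CPM are given without subtracting it. Library numbers ran in separate blocks by age, so a difference in preparation and a difference in age cannot be told apart in any comparison.

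Hopx itself (chromosome 5, 77086988 to 77115121, GRCm38) was detected above 1 CPM in 70.8% of P3 cells (exact 95% interval 58.9 to 81%), 75.9% of P7 cells (62.4 to 86.5%) and 74.6% of P14 cells (62.1 to 84.7%). Its mean level was 4.71 ± 3.35 log2(CPM + 1) at P3, 5.39 ± 3.41 at P7 and 4.91 ± 3.29 at P14. These intervals, like all others here, cover counting error only. Sox9, a transcription factor of neural stem cells and astrocytes, was detected in 91.7%, 98.1% and 100% of the cells of the 3 ages in order. Fabp7, the fatty acid binding protein of radial glia, was found in 98.6%, 100% and 98.4%. Gfap, the intermediate filament of astrocytes and radial stem cells, was found in 52.8%, 59.3% and 58.7%, and Sox2 in 73.6%, 74.1% and 65.1%.

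Some sorted cells carried transcripts of the neuronal lineage at every age. At least 3 of the fixed markers of intermediate progenitors, the dividing daughters of stem cells, were detected in 29.2% of P3 cells (19 to 41.1%), 33.3% of P7 cells (21.1 to 47.5%) and 30.2% of P14 cells (19.2 to 43.1%). Eomes, the progenitors' transcription factor, was found in 30.6%, 35.2% and 25.4%, and Dcx, a microtubule protein of immature neurons, in 30.6%, 31.5% and 19%. Globin genes, the genes of red blood cells, were detected in 4 of 72 P3 cells and 2 of 54 P7 cells. They were detected in 34 of 63 P14 cells (54%, 40.9 to 66.6%). Most markers of microglia, endothelial cells, inhibitory neurons and oligodendrocyte precursors were not analysed here.

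Transcripts of dividing cells were widespread. A cell was called cycling when at least 3 of 10 genes of mitosis and DNA replication, among them Mki67, Top2a and Cdk1, exceeded 1 CPM. This held for 77 cells, 40.7% of all. The share was 50% at P3 (36 of 72 cells, 38 to 62.0%), 38.9% at P7 (21 of 54, 25.9 to 53.1%) and 31.7% at P14 (20 of 63, 20.6 to 44.7%). The intervals of neighbouring ages overlapped, and those of P3 and P14 did too, which does not show that the shares were alike, and with 1 sample per age the difference was not tested. With every cell thinned to 50000 reads the shares were 50% (37.4 to 62.6%), 38.3% (24.5 to 53.6%) and 25% (14.7 to 37.9%). The shares depended on which of the authors' clusters, described further on, were counted. Without the cells of clusters ImA and MA they were 51.4% at P3, 45.5% at P7 and 45.2% at P14, and in clusters a1, q1 and q2 alone they were 40%, 24% and 20.7%.

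**Figure D1:**
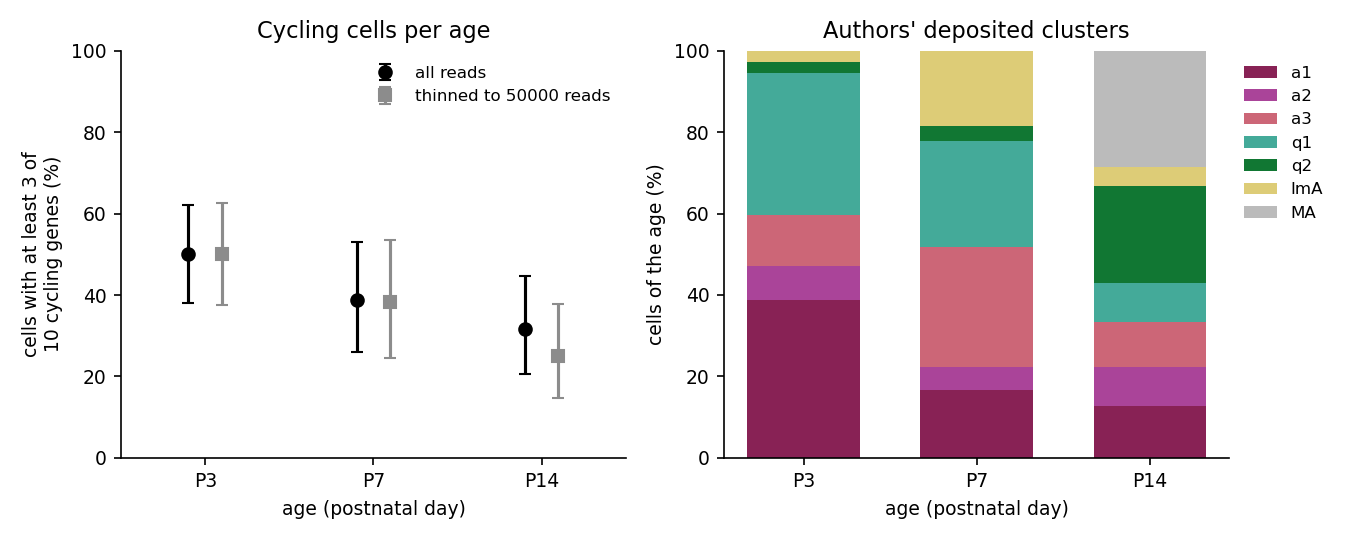
Left, percent of cells called cycling at P3, P7 and P14, with all reads (black) and after thinning to 50000 reads per cell (grey); bars are exact 95% intervals. Right, percent of the cells of each age in the 7 clusters the authors deposited; cluster MA holds 18 P14 cells and 0 cells of the other ages.

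The comparison of P14 with P3 spans the whole period. Genes of astrocyte-type transport were the most different group, and all of its 18 measured members were higher in the P14 cells, 15 of them by at least 1 log2 unit. Their median difference was 2.56 (2.84 relative to all measured genes), above 100% of 10000 random lists of matched expression. Glul, glutamine synthetase, stood at 2.94 ± 3.75 log2(CPM + 1) in P3 cells and 6.93 ± 4.01 in P14 cells, although only 61.5% of its nonzero values were whole, a sign of reads shared with other genes. Clu, a secreted chaperone, and Gjb6, a gap junction protein, differed by 3.63 and 3.61. Gjb6 was detected in 0 of 72 P3 cells, which allows a share of up to 4.17%, and in 38.1% of P14 cells. The smallest differences in the list were those of the metallothioneins Mt2 (0.47) and Mt1 (0.79).

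Astrocyte markers followed the same direction. All 14 were higher in the P14 cells, 11 by at least 1 log2 unit, with a median of 1.74 (2.01 relative to all measured genes). This list shares Aqp4, Gjb6, Slc1a2, Slc6a11 and Slc7a10 with the transport list. Ntsr2, a neurotensin receptor of astrocytes, differed by 4.65, Slc1a2, the main glutamate transporter of astrocytes, by 2.78, and Aqp4, the water channel, by 2.66. The smallest difference was that of Cbs, at 0.21. Stem cell markers went both ways, and their median of 0.25 is given no direction. In that list Apoe, which carries lipids between cells, differed by 4.04, Lpar1, a lysophosphatidic acid receptor, by 1.96 and Id4, an inhibitor of differentiation factors, by 1.54. Vim, an intermediate filament gene, differed by -2.93 and Fabp7 by -1.38. The transport and astrocyte lists depended on which of the authors' clusters were counted. In cluster MA, whose 18 cells are all from P14, astrocyte markers lay above those of the 15 P14 cells of q2 by a median of 1.96. There 11 of 14 were higher by at least 1 log2 unit, while stem cell markers differed by -0.13. The comparison over all cells therefore does not separate a change within stem cells from a different share of astrocyte-like cells. Without clusters ImA and MA the transport median was 1.06 and the astrocyte median 0.86, and averaged within clusters a1, a2, a3 and q1 they were 0.34 and 0.20, the latter inside the range of random lists, although in q1 alone the astrocyte median was 1.23, above them.

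Among single genes the highest P14 minus P3 difference by the fixed rule was that of Fam107a (chromosome 14, 8296274 to 8318023), which encodes an actin-binding protein. It was detected in 5.56% of P3 cells and 66.7% of P14 cells, and its means were 0.32 ± 1.46 and 5.02 ± 4.18. After Ntsr2 came Gpr37l1, a receptor of glial cells, at 4.14, and Apoe. Next were 2 long-chain acyl-CoA synthetases, Acsl3 at 4.02 and Acsl6 at 3.95, then Hspa2, a heat shock chaperone, at 3.95, and Htra1, a secreted protease, at 3.86. Ntm, a neural adhesion protein, differed by 3.84. Bc1 (chromosome 7, 144914470 to 144914637), a short non-coding RNA known from neurons, differed by 3.78 and was detected in 52.8% of P3 cells and 100% of P14 cells. Its level was even over the P14 cells, at 5.94 ± 1.37 log2(CPM + 1). Whether these reads came from the sorted cells themselves was not tested.

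Matrix and mitochondrial genes were also higher at P14. Of 20 adhesion and matrix genes 9 were higher by at least 1 log2 unit and 3 lower, with a median of 0.88 (1.15 relative to all measured genes). Hapln1, a link protein of the extracellular matrix, differed by 3.10 and Cd81, a membrane tetraspanin, by 2.65, against -2.26 for the proteoglycan Vcan and -2.15 for Tnc, tenascin. The direction of this list turned to -0.62 when averaged within clusters a1, a2, a3 and q1. The 13 genes encoded by mitochondrial DNA had a median of 0.91 (1.19 relative to all measured genes), and 4 of them were higher by at least 1 log2 unit. mt-Cytb, with 96.3% whole values, differed by 1.0 and mt-Nd4 by 0.91. mt-Nd3 at 3.22 and mt-Co3 at 2.62 had few whole values (21.7% and 0.617%) and are uncertain, and mt-Nd1 was close to 0 at -0.11. Averaged within clusters the mitochondrial median was 0.40.

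Ribosomal protein and proteasome genes were lower in the P14 cells. Of 32 ribosomal protein genes 29 were lower by at least 1 log2 unit, with a median of -1.90 (-1.62 relative to all measured genes) at percentile 0.00 of the random lists. Rpl4 stood at 10.52 ± 1.95 in P3 cells and 7.28 ± 4.43 in P14 cells, and was above 1 CPM in 100% of the first and 76.2% of the second. Ribosomal protein genes have many pseudogenes, so most single values are uncertain. Rpl3 differed by -2.84 and Rpl5 by -0.01, with 26.7% and 10.3% whole values. All but 1 of the 14 proteasome genes were also below their P3 level, 10 by at least 1 log2 unit, with a median of -1.77 (-1.49 relative to all measured genes). Psma7 and Psmb6, subunits of the proteasome core, differed by -2.57 and -2.49 and Psmb5 by 0.44. The other lists of protein breakdown did not share this: the lysosome median was 0.32 (0.60 relative to all measured genes), above its random lists, and the autophagy median was -0.44, inside them. As log2 ratios of mean CPM these medians were smaller, -0.72 for ribosomal protein genes and -0.39 for the proteasome, the latter inside the range of random lists. Averaged within clusters a1, a2, a3 and q1 they were -0.18 and -0.31, both inside the range of random lists. The median mitochondrial share of counts was 2.49% in P3 cells and 3.85% in P14 cells, and the authors' clusters q2 and MA, to which 15 and 18 of the P14 cells belong, had median numbers of detected genes of 1936 and 2420, against 3014 in a1.

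Early response genes, which answer stimulation within minutes, and neuronal markers were lower as well. The 9 measured immediate early genes, 4 of them lower by at least 1 log2 unit, had a median of -0.99 (-0.72 relative to all measured genes). Fos stood at -2.44, Egr1 at -1.75 and Jun at -1.61. The median was -0.60 as a log2 ratio of mean CPM, inside the range of random lists. The 4 measured markers of neuroblasts and neurons, among them Dcx (-1.16) and Prox1 (-1.11), a transcription factor of granule neurons, had a median of -1.04 (-0.77 relative to all measured genes). Of these markers 2 were lower by at least 1 log2 unit. The neuroblast median was -0.26 with a detection minimum of 5% of cells, and then lay inside the range of random lists. Averaged within clusters a1, a2, a3 and q1 it was also much smaller in size. The 34 nuclear genes of oxidative phosphorylation had a median of -0.54, with Uqcrc2 at -1.69 and Cox6a1 at 0.87, on the high side of their matched random lists, whose central 95% range was -1.41 to -0.54. It lay at the edge of that range and fell inside it with a pseudocount of 10 (-0.31), and as a log2 ratio of mean CPM its sign turned, to 0.01. The genes of the cycling class had a median of -0.89 (-0.61 relative to all measured genes), inside the range of random lists.

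By the fixed rule Rbm3, a cold-induced RNA-binding protein, had the lowest P14 minus P3 difference at -4.39, followed by Ybx1, which packages mRNA, at -3.79 and Srsf3, a splicing factor, at -3.58. Ncl, nucleolin, differed by -3.38. Rack1, a scaffold on the ribosome, differed by -3.35 and Polr2d, a subunit of RNA polymerase II, by -3.26. Others were Cav1, the coat protein of caveolae (-3.58), Tmsb10, which binds actin (-3.55), the histone variant gene H2afz (-3.50) and Fxyd6, a sodium pump regulator (-3.32). Lhx9, a developmental homeobox gene (chromosome 1, 138825186 to 138848577), was detected in 62.5% of P3 cells and 22.2% of P14 cells and differed by -3.47. Values of Rbm3, Srsf3, H2afz and Tmsb10 were whole in only 27.5%, 22.7%, 15% and 42.6% of cells with reads, so these 4 are uncertain. Cells with no reads weigh heavily in these differences. Mean CPM went from 1135 at P3 to 511 at P14 for Rbm3, from 617 to 227 for Ybx1 and from 1439 to 831 for Srsf3. Of the single-gene differences named by rule in the 3 comparisons, 48 moved by over 0.5 log2 units as log2 ratios of mean CPM. Another 8 did not, and 0 turned sign. Averaged within clusters a1, a2, a3 and q1, 49 moved by that much, 5 did not and 2 turned sign. Without clusters ImA and MA 33 moved, 23 did not and 0 turned sign. Of the 28 pathway lists with at least 4 measured members, 10 stood above and 3 below their random lists in this comparison.

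**Figure D2:**
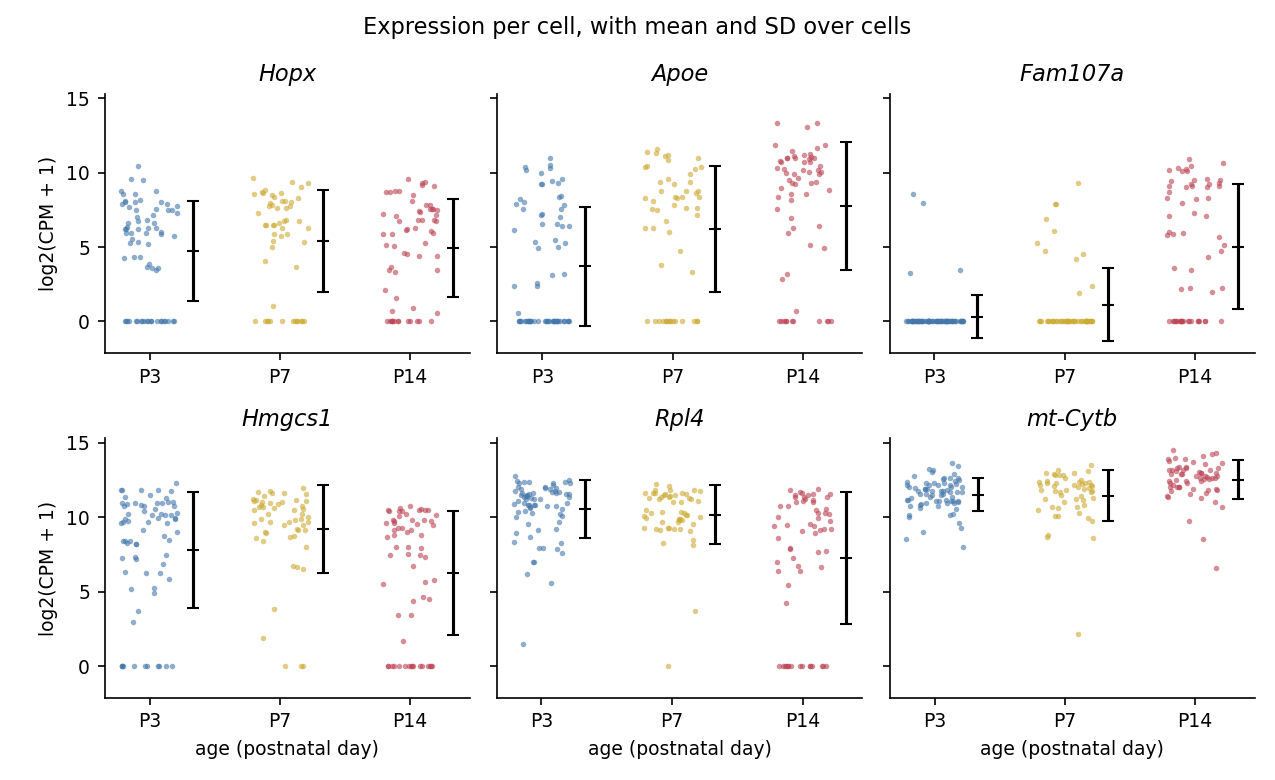
Each point is 1 cell at P3, P7 or P14 and the vertical axis is log2(CPM + 1); the bars beside the points give the mean and SD over cells. Fam107a and Apoe are higher and Rpl4 is lower in the P14 cells, where a group of cells has no Rpl4 reads, Hmgcs1 is highest at P7 (9.20), and the Hopx means are 4.71, 5.39 and 4.91.

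The comparison of P7 with P3 covers the first days. Genes of cholesterol synthesis stood out, and all 19 were higher in the P7 cells, 13 by at least 1 log2 unit, with a median of 1.47 (1.21 relative to all measured genes) above 100% of the random lists. Insig1, which senses sterols, stood at 2.44 ± 3.02 log2(CPM + 1) in P3 cells and 4.93 ± 2.71 in P7 cells. Sc5d differed by 2.36 and Fdft1, squalene synthase, by 2.18. Fatty acid synthesis genes, 11 measured, had a median of 1.07 (0.80 relative to all measured genes), led by Fasn, fatty acid synthase, at 2.38 and Elovl5 at 1.96. As a log2 ratio of mean CPM the cholesterol median was 0.75, and averaged within clusters a1, a2, a3 and q1 it was 0.84. The same average for fatty acid synthesis was 0.54.

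Glial genes were already higher at P7. The transport list had a median of 1.53 (1.27 relative to all measured genes), with 13 of 18 genes higher by at least 1 log2 unit, and Clu differed by 2.65 and Kcnj10, a potassium channel, by 2.60. Mt1 was against this direction at -0.34. Astrocyte markers had a median of 0.93 (0.67 relative to all measured genes), with Hepacam, an adhesion protein, at 1.59 and Gjb6 at 0.00. Adhesion and matrix genes had a median of 1.03 (0.76 relative to all measured genes), with Hapln1 at 2.14, Vcan at 1.88 and the integrin subunit Itga6 at -0.53. Stem cell markers had a median of 0.68 (0.42 relative to all measured genes), with Apoe at 2.49 and Vim at -0.68. Oxidant defence genes also had a median of 0.68, with Sod2, the mitochondrial superoxide dismutase, at 1.57 and Txn1, thioredoxin, at -0.67. Averaged within clusters, the transport median was 0.70, and those of astrocyte markers (0.05), adhesion and matrix (0.20), stem cell markers (0.09) and oxidant defence (0.00) lay inside the range of random lists. That average joins clusters that differed, and its a2 part rests on 3 P7 cells. In q1 alone the medians of astrocyte markers (1.45) and of adhesion and matrix (1.04) stood above their random lists, while in a1, a2 and a3 they were -0.17, -0.64 and -0.02 for the former and -0.17, -0.59 and 0.09 for the latter, inside them.

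Medians of ribosomal protein and cycling genes lay below 0 for P7 against P3, with few members lower by 1 log2 unit. The ribosomal protein median, with 4 of 32 genes lower by that much, was -0.56 (-0.83 relative to all measured genes), with Rps2 at -1.46 and Rpl5 at 1.0, and averaged within clusters it was -0.32, inside the range of random lists. The cycling class, with 1 of 10, had a median of -0.55 (-0.82 relative to all measured genes), with Cdk1, the kinase of mitotic entry, at -1.04 and Mki67 at -0.98, against Ccna2, cyclin A, at 0.63. The longer S phase and G2/M lists both had medians of -0.34, which are given no direction. The sign of the cycling class turned to 0.32 in cells from even well columns and to 0.02 as a log2 ratio of mean CPM. In this comparison 5 pathway lists stood above and 5 below their random lists.

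By the fixed rule the largest single difference between P7 and P3 was that of Tsix (chromosome X, 103431517 to 103484957), at 3.76. Its mean CPM was 873 at P3 and 1712 at P7, and it was above 1 CPM in 69.4% and 98.1% of cells. Tsix is antisense to Xist, the RNA of the inactive X chromosome, and the strand of the reads is not stated, so its values cannot be separated from Xist. Xist was detected in 58.3% of P3 cells, 83.3% of P7 cells and 54% of P14 cells. A transcript of the Y chromosome was detected in 19 of 72 P3 cells, 1 of 54 P7 cells and 19 of 63 P14 cells. Among these, 3 P3 cells, 1 P7 cell and 6 P14 cells also had Xist. Whether such wells held RNA of more than 1 cell was not tested. Beside this imbalance in sex-linked transcripts, the other highest genes were Lxn, a carboxypeptidase inhibitor (3.46), Asrgl1, an asparaginase (3.32), the motor protein gene Myo10 (3.19), the mitochondrial carrier gene Slc25a18 (2.96), Ctnnd2, a catenin (2.94), and Tmbim4 (2.85). The lowest were Lhx9 (-2.46), the chromatin protein gene Hmgb2 (-2.03, with 16.4% whole values), the imprinted adaptor gene Grb10 (-1.90), Bzw2 (-1.90), Exosc8, an exosome subunit (-1.87), Tnfrsf19 (-1.87), Id2 (-1.85) and Riok2, a ribosome assembly kinase (-1.85).

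The comparison of P14 with P7 covers the second interval. Here cholesterol synthesis was lower in the older cells, with 11 of 19 genes lower by at least 1 log2 unit and a median of -1.26 (-0.71 relative to all measured genes). Hmgcs1, which makes the precursor of mevalonate, stood at 9.20 ± 2.93 log2(CPM + 1) in P7 cells and 6.26 ± 4.18 in P14 cells, Fdps differed by -2.55, Fdft1 by -2.34 and Sc5d by -2.30. As a log2 ratio of mean CPM the median was -0.42 and lay inside the range of random lists, and averaged within clusters it was -0.57. The imbalance in sex-linked transcripts at P7 bears on this comparison too, so sex stays open. Proteasome genes had a median of -1.72 (-1.18 relative to all measured genes), with 13 of 14 lower by at least 1 log2 unit and Psmb7 at -2.87. That median was -0.26 as a log2 ratio of mean CPM and -0.30 averaged within clusters, both inside the range of random lists.

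Mitochondrially encoded and glial genes were higher in P14 than in P7 cells. The mitochondrial list had a median of 1.07 (1.62 relative to all measured genes), with mt-Cytb at 1.06 and mt-Nd5 at -0.49, and it was 0.51 in even well columns. The transport list had a median of 0.91 (1.45 relative to all measured genes), with Gjb6 at 3.61 and Glul at 2.34, against Kcnj16, a potassium channel, at -0.86. Astrocyte markers had a median of 0.72 (1.27 relative to all measured genes), with Ntsr2 at 3.20 and Agt, angiotensinogen, at -0.28. Without clusters ImA and MA these glial medians, with no shift subtracted and so to be set against 0.91 and 0.72, were -0.0039 and 0.03. Averaged within clusters they were -0.30 and 0.06, inside the range of random lists. In q1 alone they were 0.97 and 0.80, above their random lists, and in a3 the transport median was -1.75, below them. The 34 nuclear genes of oxidative phosphorylation had a median of -0.62, close to all measured genes at -0.08 relative to them, with Uqcrc2 at -3.03 and Ndufa4 at 0.23. This median lay at percentile 98.33, on the high side of its matched random lists, and was much smaller in size as a log2 ratio of mean CPM. In this comparison 5 pathway lists stood above and 2 below their random lists.

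The highest single genes for P14 against P7 were Bc1 at 4.76, Fam107a at 3.89, Gjb6 and Ntsr2. Selenop, a secreted selenium carrier, differed by 2.80, the zinc transporter gene Slc39a12 by 2.69, Htra1 by 2.62 and Omg, a myelin glycoprotein, by 2.56. Slc39a12 and Omg turned to -0.12 and -0.01 when averaged within clusters. The lowest was Vcan (chromosome 13, 89655312 to 89742509), versican, detected in 81.5% of P7 cells and 31.7% of P14 cells, at -4.14. Next were a gene whose name had become a date in the deposited table (-3.91), Dpysl3, a neuronal growth protein (-3.86), Idh1, the cytosolic isocitrate dehydrogenase (-3.73), Gtf2a1 (-3.52), Cav1 (-3.48), Rtraf (-3.18) and Hnrnpc (-3.14).

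**Figure D3:**
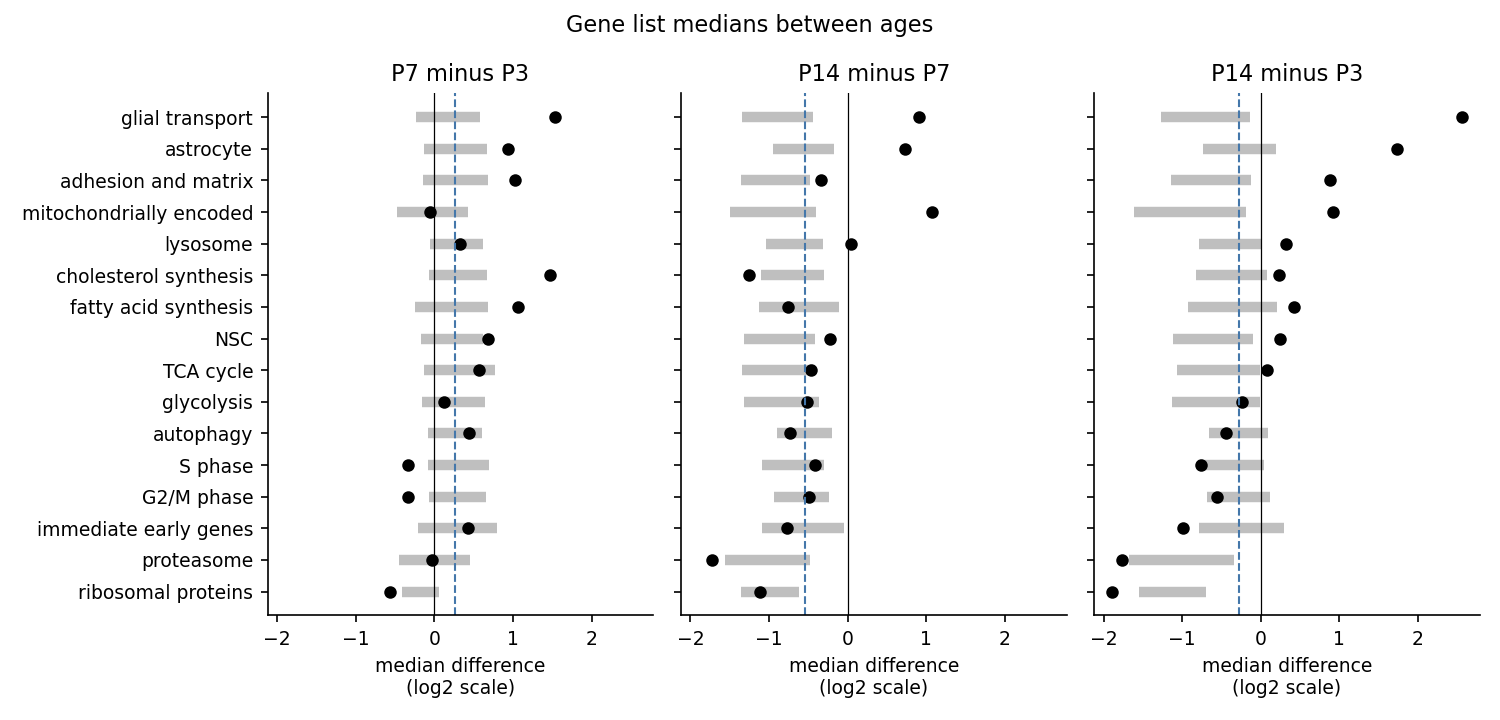
Horizontal axis, median over measured members of the log2 difference between 2 ages, for 16 gene lists; grey bars give the central 95% range of 10000 random lists of matched expression and the dashed blue line the median of all measured genes. Cholesterol synthesis lies right of its grey bar for P7 minus P3 (1.47) and left of it for P14 minus P7 (-1.26), and ribosomal proteins lie left of it for P14 minus P3 (-1.90).

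The authors' deposited table places each cell in 1 of 7 clusters, named a1, a2, a3, q1, q2, ImA and MA, and gives a pseudotime, an ordering of cells by expression, to the 109 cells of a1, q1 and q2. Clusters and pseudotime were made from the same expression values that are compared here. The cycling call was met in 62.2% of a1 cells, 93.3% of a2 cells and 84.4% of a3 cells, and in 11.1% of q1, 5.26% of q2, 13.3% of ImA and 0 of the 18 MA cells. Cluster a1 held 28 P3, 9 P7 and 8 P14 cells and q1 held 25, 14 and 6. Cluster q2 held 2, 2 and 15, and all 18 MA cells were from P14. The mean level of the ribosomal protein genes in P14 cells was 9.84 ± 0.43 log2(CPM + 1) in a1, 8.90 ± 0.56 in q1, 6.64 ± 1.33 in q2 and 5.79 ± 1.95 in MA. Glial transport genes stood at 3.27 ± 1.68 in a1, 7.06 ± 0.41 in q1, 7.04 ± 2.25 in q2 and 9.23 ± 0.82 in MA.

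Within cluster q1 the ages could be compared among cells that the authors had grouped together. Glial transport genes were higher in the 6 P14 cells than in the 25 P3 cells, with a median difference of 1.82, with Clu at 5.38 and Kcnj10 at 4.09, and with Slc4a4, a bicarbonate transporter, at -1.26. Mitochondrially encoded genes were higher by a median of 1.65, with mt-Nd4 at 1.65 and mt-Cytb at 1.17 against mt-Nd6 at -0.76. Stem cell markers had a median of 1.09, with Lpar1 at 7.36, Apoe at 3.15 and Gfap at 2.43, against Ednrb, an endothelin receptor, at -2.75. Astrocyte markers had a median of 1.23, at percentile 99.85 of the random lists. Immediate early genes had a median of -2.14, with Egr1 at -2.66 and Fos at -2.14 against Ier5 at 1.72, and the proteasome one of -1.05. The ribosomal protein median was -0.23, at percentile 38.7 of the random lists. Cholesterol synthesis genes within q1 had a median of 1.38 for P7 against P3 and -2.03 for P14 against P7, with Sqle, squalene epoxidase, at 2.83 and -5.49. The q1 cells of the ages were not at the same place in the authors' ordering, since their median pseudotime was 33.1 at P3, 33.8 at P7 and 47.5 at P14. Estimated reads per q1 cell ranged from 31286 to 1636256 at P3, 26714 to 1816241 at P7 and 192341 to 1282649 at P14. Most P3 cells of q1 lay below the lowest P14 cell. No value within q1 was thinned to equal reads, so depth stays open for these differences. With 6 P14 cells, single values here are coarse. The other clusters with at least 3 cells of every age, a1, a2 and a3, did not all share the q1 differences. For P14 against P3 the glial transport median was 0.14 in a1, -0.16 in a2 and -0.55 in a3, that of astrocyte markers 0.10, -0.05 and 0.37, that of stem cell markers 0.35, 0.00 and -0.91, and that of mitochondrially encoded genes -0.02, -0.22 and 0.33. For immediate early genes it was -1.11, -0.06 and -0.73 and for the proteasome 0.19, 0.09 and -0.12. For cholesterol synthesis P7 against P3 gave 0.45, -0.11 and 1.02 and P14 against P7 gave -0.81, 0.93 and -0.85.

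**Figure D4:**
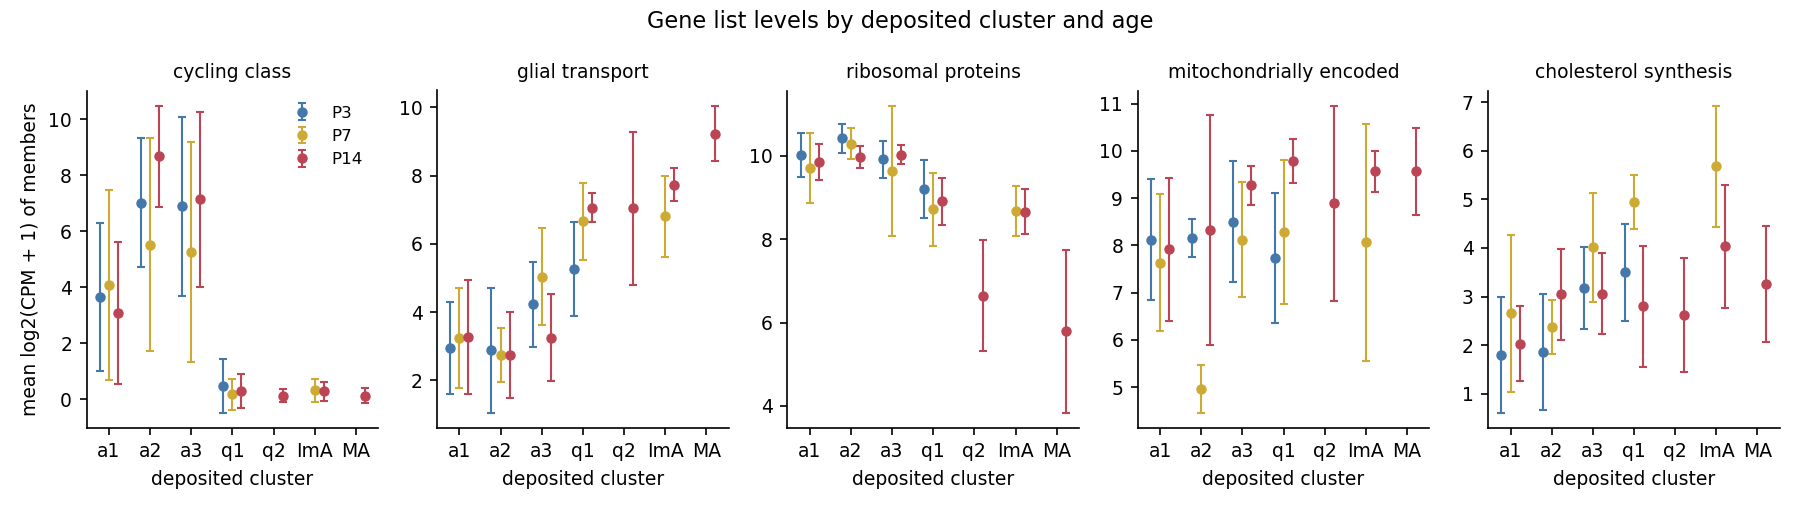
Mean log2(CPM + 1) over the members of 5 gene lists in each deposited cluster at P3, P7 and P14, for clusters with at least 3 cells of that age; bars are the SD over cells. Ribosomal protein genes are lowest in the P14 cells of q2 (6.64) and MA (5.79), and cholesterol synthesis in q1 is highest at P7 (4.95).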

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

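The alternatives on thinned reads, scaling by exon length and deposited clusters were chosen after seeing the data. Of 662 alternative values of 37 list medians, 560 moved by at most 0.5 log2 units, 96 moved further and 6 turned the sign of a median over 0.5; for single genes named by rule these counts were 415, 421 and 2. A median of 0.5 or less was not given a direction, a limit on what counts as a turn that was set after a first look at the alternatives; among the 13 such medians the sign turned in 41 of 234 alternatives. In 136 of the 662 a list fell inside the range of its random lists, most often when averaged within clusters (22 of 37). Clusters were built on the same expression, so averaging within them also removes differences that define them. The average covers a1, a2, a3 and q1 and leaves out q2, ImA and MA, which hold 15, 3 and 18 of the P14 cells. Scaling by exon length and leaving out P3 well column 10 moved no list median by over 0.5. Keeping only cells with a Y-linked transcript gave no value, as P7 has 1 such cell, in which Xist was detected too. No cluster was named as another cell type to be left out, and the rescaled total gives no value for the mitochondrial and ribosomal lists. No paired analysis was possible because the labels' numbers count libraries and are not shared between ages. Depth was low in some single cells: 6 P3, 7 P7 and 3 P14 cells had under 50000 reads.

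Where not stated otherwise the cause of the shifts below was not tested; subsets hold fewer cells and stricter minimums fewer genes. Averaged within clusters a1, a2, a3 and q1, P14 minus P3 medians were 0.40 for mitochondrially encoded genes, -0.18 for ribosomal proteins, -0.31 for the proteasome, -0.62 for adhesion and matrix, 0.34 for glial transport, 0.20 for astrocyte markers and -0.12 for neuroblast markers. For P7 minus P3 they were 0.54 for fatty acid synthesis, 0.84 for cholesterol synthesis, 0.0048 for oxidant defence, 0.20 for adhesion, 0.70 for glial transport, 0.090 for stem cell and 0.047 for astrocyte markers. For P14 minus P7 they were -0.57 for cholesterol synthesis, -0.30 for the proteasome, -0.30 for glial transport and 0.062 for astrocyte markers, with Slc39a12 at -0.12 and Omg at -0.011. Without clusters ImA and MA the P14 cycling share was 45.2%; P14 minus P3 was -1.06 for ribosomal proteins, 0.12 for adhesion, 1.06 for glial transport and 0.86 for astrocyte markers, and P14 minus P7 was -0.0039 for glial transport and 0.028 for astrocyte markers. In a1, q1 and q2 alone the P7 cycling share was 24%, P7 minus P3 was 0.021 for oxidant defence and 0.037 for stem cell markers, glial transport was 2.01 for P14 minus P3 and astrocyte markers 0.15 for P14 minus P7.

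As log2 ratios of mean CPM, in which cells with many reads of a gene count most, P7 minus P3 was 0.024 for the cycling class, 0.75 for cholesterol synthesis and 1.0 for glial transport. P14 minus P7 was -0.030 for nuclear oxidative phosphorylation, -0.42 for cholesterol synthesis and -0.26 for the proteasome. P14 minus P3 was 0.0059 for nuclear oxidative phosphorylation, -0.72 for ribosomal proteins, -0.39 for the proteasome and 2.36 for astrocyte markers. With a pseudocount of 0.1 cholesterol synthesis was 2.22 (P7 minus P3), the proteasome -2.34 (P14 minus P7) and -2.30 (P14 minus P3) and astrocyte markers 2.49 (P14 minus P3). With 10, by its construction smaller, cholesterol synthesis was -0.75 and the proteasome -1.09 (P14 minus P7), and P14 minus P3 was -1.25 for the proteasome, 1.83 for glial transport and 1.02 for astrocyte markers. Centred on all measured genes, which shifts every list alike, P14 minus P7 was -0.078 for nuclear oxidative phosphorylation, 1.62 for mitochondrially encoded genes, -0.71 for cholesterol synthesis, -1.18 for the proteasome, 1.45 for glial transport and 1.27 for astrocyte markers.

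In cells not called cycling P14 minus P3 was -2.66 for ribosomal proteins, -2.40 for the proteasome, 1.45 for adhesion, 3.14 for glial transport and 2.40 for astrocyte markers, and P14 minus P7 was -2.41 for the proteasome and 1.65 for glial transport. In the shared range of detected genes P14 minus P7 was -1.21 for the proteasome, 1.63 for glial transport and 1.23 for astrocyte markers. In even well columns the cycling class was 0.32 and cholesterol synthesis 2.07 (P7 minus P3), mitochondrially encoded genes 0.51 and glial transport 1.5 (P14 minus P7), and glial transport 3.14 (P14 minus P3). In odd columns the cycling class was -1.08 and oxidant defence 0.028 (P7 minus P3), mitochondrially encoded genes 1.61 (P14 minus P7) and glial transport 1.91 (P14 minus P3). With a minimum of 50% of cells cholesterol synthesis was -1.79 (P14 minus P7), immediate early genes -1.75 and astrocyte markers 2.44 (P14 minus P3). Neuroblast markers were -0.26 (P14 minus P3) with a minimum of 5% and -0.26 with no filter. Thinned to 50000 reads, adhesion was 1.61 (P7 minus P3). Resolution 0.3 gave 2 clusters and resolution 1 gave 8.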

Other observations

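The Id genes, targets of BMP signals that hold back differentiation, differed between P3 and P14 in opposite directions. Id2 differed by -2.31, Id3 by -2.03 and Id1 by -1.47, and Id4 by 1.54. The list of BMP and TGF-beta pathway genes that holds them had a median of -0.50 at percentile 40.6, inside its random lists. Among Notch pathway genes Hes1, a Notch target, differed by -1.26 and the receptor gene Notch2 by 2.15, with a list median of -0.10 at percentile 68.7. Of 8 measured developmental regulators 5 were lower by at least 1 log2 unit, among them Sox11 (-2.30), a transcription factor of immature neurons, with Mycn at 0.06, and the list lay at percentile 9.93.

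All tests in the next 3 paragraphs were chosen after the result was seen, except 3. These are the random lists matched on exon length, the test on sex and that on the ratio of globin genes. The scaling by exon length among the alternatives is a separate step. Age itself and the unrecorded preparation of each age stay open for every pattern, since they cannot be told apart here. In comparisons with P7, where 1 cell had a Y-linked transcript, sex stays open too.

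Ribosomal protein genes were lower and mitochondrially encoded genes higher at P14 than at P3. The median read count was higher in P14 cells (333223) than in P3 cells (177011), which argues against fewer reads as the source of lower ribosomal values. Thinning cells to equal reads gave a ribosomal median of -2.05, which adds little to this. Thinning does not even out the RNA content or quality of cells, which was not tested. The list lay at percentile 0.0100 among random lists matched on expression and exon length, which argues against exon length so measured. Exon length here was the union of all annotated exons of a gene and not the length of its transcripts. A bias by transcript length therefore stays open. The mix of deposited clusters stays open for the ribosomal genes. Averaged within clusters a1, a2, a3 and q1 the median was -0.18, with medians of -0.43 to 0.10 in single clusters, although those clusters rest on the same values. The average leaves out q2 and MA, which hold 15 and 18 of the P14 cells and had the lowest levels of these genes. It cannot tell a changed mix from a change with age that places cells in those clusters. For mitochondrially encoded genes the mix stays open, with a median of 0.40 for gene differences averaged within clusters, beside list medians of -0.02 in a1, -0.22 in a2, 0.33 in a3 and 1.65 in q1, whose 6 P14 cells lie later in the authors' ordering. Reads shared with pseudogenes stay open for most of the ribosomal genes.

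Cholesterol synthesis genes were higher at P7 than at P3. Thinned to equal reads their median was 1.62, which argues against depth. The mix of clusters stays open in part, as the median of gene differences averaged within clusters was 0.84, beside list medians of 0.45 in a1, -0.11 in a2 with 3 P7 cells, 1.02 in a3 and 1.38 in q1. Sex could contribute, because 1 P7 cell had a Y-linked transcript against 19 at each other age. Cells with Xist and no Y-linked transcript exceeded those with the reverse by 0.76 within P14 (percentile 99.98 of random lists) but by -0.21 within P3, so sex is left open. For P14 against P7, where cholesterol synthesis was lower, the same imbalance leaves sex open too.

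Globin transcripts were found in 54% of P14 cells and in 5.56% of P3 cells. After thinning the shares were 46.7% and 3.03%, with intervals apart, which argues against depth. RNA of red blood cells in the P14 wells is a candidate source, although the sort on the Hopx reporter would remove such cells themselves, and no red blood cell marker other than globin genes was analysed here. The share over all P14 cells lay in the interval of 7 of 7 clusters, a weak test since clusters held 3 to 18 cells. The log2 ratio of alpha to beta globin counts differed by 1.20 between the 2 sets of clusters (2.10 and 0.89), which decides nothing, and no biological explanation was tested.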
